A study of Mus musculus with 95 samples.

How the data were processed

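Total RNA of mouse lung homogenates was labelled with biotin by in vitro transcription with reagents for Affymetrix arrays, per the labels' protocols. The deposited table holds 1 intensity per probe set and array on a linear scale for 12487 probe sets and 95 arrays, with 1 missing value. The method that summarised probes into these intensities is not given in the sources used here. After leaving out 2% of values at each end, the mean of each array lay between 100.05 and 100.07, so the deposited intensities had been scaled to a common mean. Array medians spanned 0.39 on the log2 scale.

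Intensities were used as deposited, with no further scaling, as log2(intensity + 8); the offset of 8 was set from the 20th percentile of all values, 6.76. The platform annotation gave 1 gene symbol for 10854 probe sets, several for 396 and none for 1236, of which 43 are control probe sets; 1 probe set with the missing value was left out. Of the named probe sets, 10838 had their Entrez identifier in the RefSeq gene table. Each of the 8252 genes was represented by its brightest probe set, and 2075 genes had several; where another probe set of a named gene that passed had the opposite sign, the text gives both. Symbols can be those of an old array design, and no genome coordinates were used.

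Groups were taken from the labels: strain, days of exposure and exposure. Per the design text, exposed and unexposed mice were kept in separate cages in experiments 1 to 3, and the unexposed C57BL/6 group of day 32 holds 2 arrays here. For the mice of days 39 and 75 no experiment is given in the sources used here. Comparisons within 1 experiment were fitted on the groups of that experiment, day 35 against day 34 on 4 groups of experiments 2 and 4, the unexposed strains of day 14 on their groups from experiments 3 and 4, and days 39 and 75 on the 7 groups of days 32, 39 and 75. The 15 comparisons were made with lmFit and eBayes of limma 3.58.1 in R 4.3.3, which pools the spread over groups, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 29 gene lists, of which each had at least 5 measured genes, were tested with fry, with adjustment over the 29 lists of a comparison. Fry asks whether the genes of a list move on balance in one direction and does not compare the list with other genes. Its rotations keep the correlation between genes. The alternative was camera with an estimated correlation, which asks another question, whether a list moves more than the other genes. Each p given with an estimated correlation is from camera. A list that passed fry and not camera therefore did not fail because of correlation alone. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

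The lists, the comparisons, the alternatives named next and the rule for naming genes were fixed before the data were examined. That rule took Cd40lg, the 10 largest rises and 6 largest falls among called genes brighter than the median gene and on one side of the mean of the unexposed arrays in every exposed array (without that condition for a comparison of effects), up to 4 called members of each list or else the 2 with the smallest p, and 22 genes always allowed. Genes named outside it are said to be so. Alternatives were offsets of 2 and 32, a filter that keeps 5502 brighter genes, quantile normalization over all arrays, 1 fit of all 95 arrays, the mean of all probe sets of a gene, the replicate number as a block and leaving out each array in turn. Where leaving out arrays leaves 1 in a group, the lone array is assumed to vary like the other groups.

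Further alternatives were chosen after seeing the data, as were their marker lists of 9 squamous epithelium and 10 skeletal muscle genes and the score of 7 that separates arrays with squamous transcripts. They were the squamous score as a covariate, both tissue scores as covariates, the log2 ratio of the 3' to the 5' Gapdh probe set as a covariate, and leaving out the arrays with squamous transcripts, alone or with the unexposed mice of days 34 and 41 pooled. Both tissue scores had been tried first and were set aside for the squamous score alone after their counts were seen; they were then restored, so both are reported throughout.

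The fits were tested on simulated data made from the arrays, with 200 of 8252 genes changed. Noise was drawn independently for each gene, so the simulated genes did not vary together as real ones can. For day 32 in C57BL/6 mice, 28, 46, 48 and 50 of 50 genes changed by 1, 2, 3 and 4 on the log2 scale were found, with 11 false calls among 8052 unchanged genes. For day 34 these were 44, 49, 50 and 50 with 9 false calls, for day 14 they were 48, 49, 49 and 50 with 12 false calls, and for CD40L-KO mice at day 35 they were 41, 50, 50 and 50 with 15 false calls. A raised list was found in each of the 4 simulations and 0 of 28 unchanged lists was called. No pair of arrays held identical values (0 pairs), and correlations between arrays ranged from 0.819 to 0.988. Quantile normalization moved the median of all genes by less than 0.1 in each comparison. No array was left out of the main comparisons.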

Results

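Lung homogenates of mice housed with a cage mate infected with Pneumocystis murina, a fungus that lives in mouse lung, and of unexposed mice were profiled on 95 single-colour expression arrays, 60 from exposed and 35 from unexposed mice. The mice were of the C57BL/6 strain or lacked CD40 ligand (CD40L-KO), a T cell surface protein that activates B cells and antigen-presenting cells through CD40. The arrays fell into 19 groups of strain, day and exposure with 2 to 10 mice each; 16 groups came from 4 experiments, and for the 3 groups of days 39 and 75, with 8 mice, no experiment is stated. Each array reported 12487 probe sets, reduced to 8252 genes, and its median intensity lay between 35.5 and 46.3. For arrays the number of mice limits the precision. Changes are differences of mean log2(intensity + 8), which understates the change of dim genes, and are given with their standard error (SE) and limma's adjusted p. Where a change is said to be in 3 of 3 mice or the like, those exposed mice lay on its side of the mean of the unexposed mice. For genes named for the size of their change the naming rule required this of every exposed mouse, so it adds no support. In experiments 1 to 3 exposed and unexposed mice were kept in separate cages, and the cage of each mouse is not in the labels, so cage and exposure cannot be told apart and the p-values treat mice as independent.

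The transcript of the deleted gene, Cd40lg, lay between 3.05 and 3.75 on all 95 arrays, close to the floor of 3 set by the offset, in both strains. Its level therefore does not check the strain labels. Transcripts typical of squamous epithelium, such as keratins 4 and 13, averaged at least 8.1 on 16 arrays and at most 5.25 on the others. Those 16 arrays also carried more skeletal muscle transcripts, with a mean score of 8.01 ± 0.77 (SD, n = 16) against 5.03 ± 0.68 on the remaining arrays. They included 4 of the 5 unexposed C57BL/6 mice of day 34 and 2 of the 3 unexposed CD40L-KO mice of day 32. On 17 arrays, all those of 5 groups, the Y-linked Eif2s3y exceeded the X-inactivation transcript Xist although the labels call the mice female. These groups were the CD40L-KO mice of days 39 and 75, the exposed CD40L-KO mice of day 35, the unexposed CD40L-KO mice labelled day 14 and the C57BL/6 mice of day 75.

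**Figure D1:**
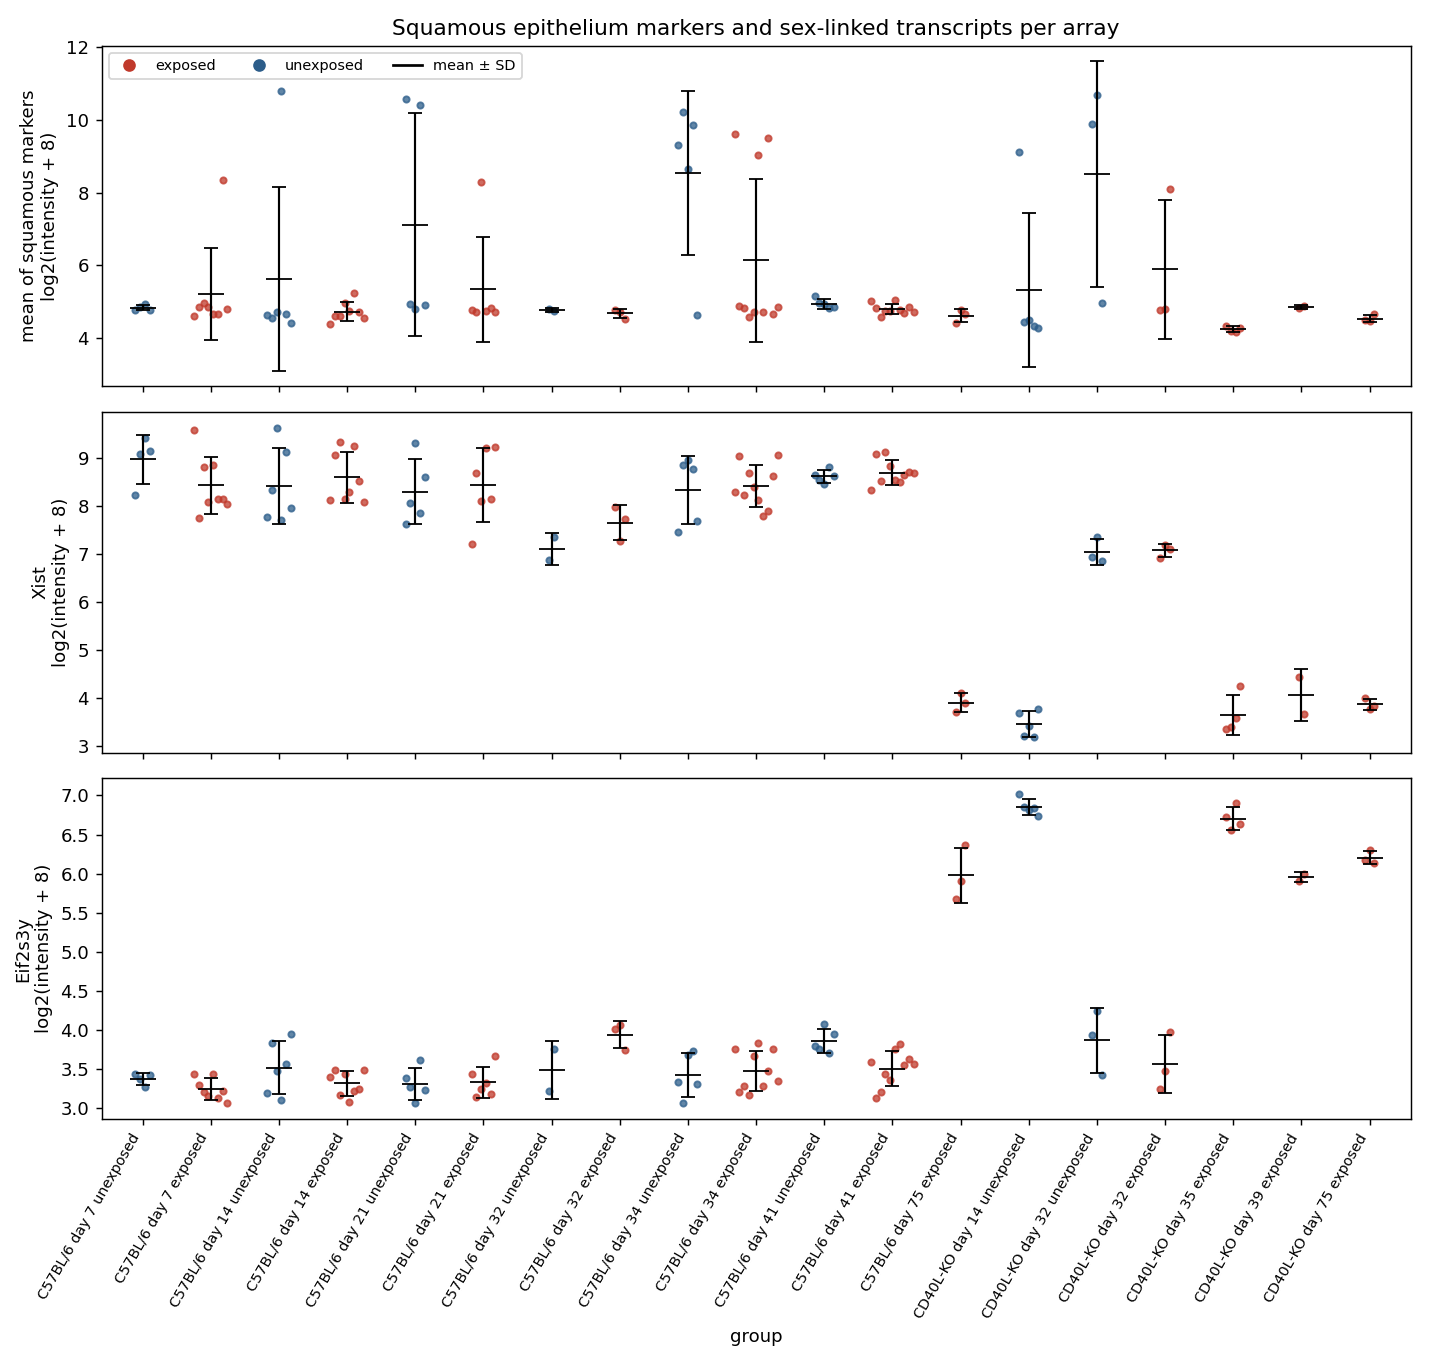
Mean of 9 squamous epithelium markers, Xist and Eif2s3y on each array, as log2(intensity + 8), by group on the horizontal axis, with points for mice and bars for mean ± SD. The 16 arrays at or above 8.1 in the top panel stand apart from the rest, and 17 arrays have Xist at or below 4.44 where the others are at or above 6.85.

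The first comparison asked what 32 days of exposure changed in C57BL/6 lung. Saa3, Clca1 and the chemokine genes Cxcl9, Ccl2, Ccl7 and Ccl8 were among the genes higher in the 3 exposed than in the 2 unexposed mice. Saa3 (Entrez gene 20210), an acute-phase serum amyloid, was higher by 5.3 (SE 0.45, adjusted p = 0.00101) and Cxcl9 (17329), an interferon-gamma-induced chemokine that draws T cells, by 4.5 (SE 0.31, adjusted p = 0.000287), in 3 of 3 mice. Clca1 (23844), a goblet cell product, rose by 5.01 (SE 0.82), although its dimmer probe set moved by 0.06; that probe set stayed between -0.7 and 0.59 in every comparison where Clca1 is named. The monocyte chemokines Ccl2, Ccl7 and Ccl8 rose by 3.76, 3.62 and 3.75. In the list of Th1 and interferon-gamma response genes, 15 of 33 rose and 18 did not pass, and 26 rose when adjusted over the list alone. Its fry test gave adjusted p = 0.00194. Camera, which compares a list with the other genes, gave adjusted p = 0.0652 with an estimated correlation. Of 34 macrophage and monocyte genes 14 rose, 24 when adjusted over the list alone, with 1 lower there (fry adjusted p = 0.00457, adjusted p = 0.0652 with an estimated correlation). The complement genes C1qa, C1qb and C1qc rose by 1.54, 1.83 and 1.8, and the MHC class II genes H2-Eb1 and H2-Ab1 by 1.55 and 1.31. Cell cycle genes rose in 5 of 41 cases, 28 when adjusted over the list alone, among them Cdk1 by 2.03 (fry adjusted p = 0.0128, adjusted p = 0.091 with an estimated correlation). Pon1, a lipoprotein-associated esterase, fell by 2.79 and the scavenger receptor Cd36 by 1.11, the latter with its other probe set at 0. Ifng itself differed by 1.14 (SE 0.34, adjusted p = 0.123) and Il13 by 0.02. In all 111 genes were higher and 25 lower. The count was 52, 584 and 39 without exposed replicate 1, 2 and 3, and 9 and 6 without unexposed replicate 1 and 2; it was 733 with all arrays in 1 fit, 209 with the higher offset, 225 without dim genes, 4 with the squamous and skeletal muscle scores as covariates and 4 without the squamous arrays of the fit, which are all CD40L-KO.

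The same exposure in CD40L-KO mice, with 3 mice in each arm, changed few genes past the threshold. Ppm1b, a protein phosphatase, rose by 1.18 (SE 0.13, adjusted p = 0.0127), the MHC class II gene H2-Ob by 1.08, the sorting nexin Snx2 by 0.96 and adenosine kinase, Adk, by 0.93, each in 3 of 3 mice. Ensa rose by 0.99 and Ddx49 fell by 1.29, and these names were chosen after their values were seen. Ddx49 averaged 3.84 in the exposed mice, near the floor of 3, and 5.14 in the unexposed mice. In unexposed C57BL/6 mice it averaged 3.68, so the unexposed CD40L-KO mice stood apart. Cxcl9 differed by 0.68 (SE 0.28, adjusted p = 0.32), Clca1 by -0.23 (SE 0.74) and Cxcl10 by 0.41 (SE 0.51). Squamous transcripts were on 1 of the 3 exposed and 2 of the 3 unexposed arrays, and the Gapdh 3' to 5' ratio, a sign of RNA quality, was 0.92 to 1.0 in exposed and 1.16 to 1.37 in unexposed mice. Limma's fry test called 0 of the 29 lists, as did camera, and 1149 genes had an unadjusted p under 0.05 where 412.6 are due by chance. The 6 calls became 0 without exposed replicate 1 or 3 or unexposed replicate 2, 1 without exposed replicate 2 and 54 without unexposed replicate 3. They were 0 with the squamous score, with both tissue scores or with the Gapdh ratio as covariates and without squamous arrays, which left 1 unexposed array, 2 and 13 with the lower and higher offset, 26 without dim genes, 3 with the mean of all probe sets, 86 with all arrays in 1 fit and 3, of which 2 higher and 1 lower, with quantile normalization.

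Whether the 2 strains responded differently was tested as the difference of their day 32 effects. The effect on Saa3 was 5.58 smaller in CD40L-KO mice, a log2 difference of -5.58 (SE 0.6, adjusted p = 0.00773), and that on Cxcl9 differed by -3.81 (SE 0.41, adjusted p = 0.00773). Pigr, which carries IgA across epithelium, differed by -2.21 (SE 0.29), the interferon-inducible GTPase Iigp1 by -2.75 (SE 0.4) and the mucin Muc5ac by -1.66 (SE 0.26). Ppm1b went the other way, by 1.52, as did the prostaglandin-degrading enzyme Hpgd, by 1.46. For Clca1 the difference of -5.24 had SE 1.1 and adjusted p = 0.0999, with its other probe set at 0.28. Of the 33 Th1 and interferon-gamma genes 2 had a lower effect, 18 when adjusted over the list alone (fry adjusted p = 0.0326, adjusted p = 0.156 with an estimated correlation). In all, 4 genes had a higher and 10 a lower effect. The count was 3, 197 and 6 without C57BL/6 exposed replicate 1, 2 and 3, 2 and 5 without C57BL/6 unexposed replicate 1 and 2, 5, 3 and 3 without CD40L-KO exposed replicate 1, 2 and 3, and 3 and 6 without CD40L-KO unexposed replicate 1 and 2. It was 3 and 27 with the lower and higher offset, 25 without dim genes, 9 with the mean of all probe sets, 301 with all arrays in 1 fit, 3 with the squamous score, 1 with both tissue scores and 0 with the Gapdh ratio as covariates, and 0 without squamous arrays.

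**Figure D2:**
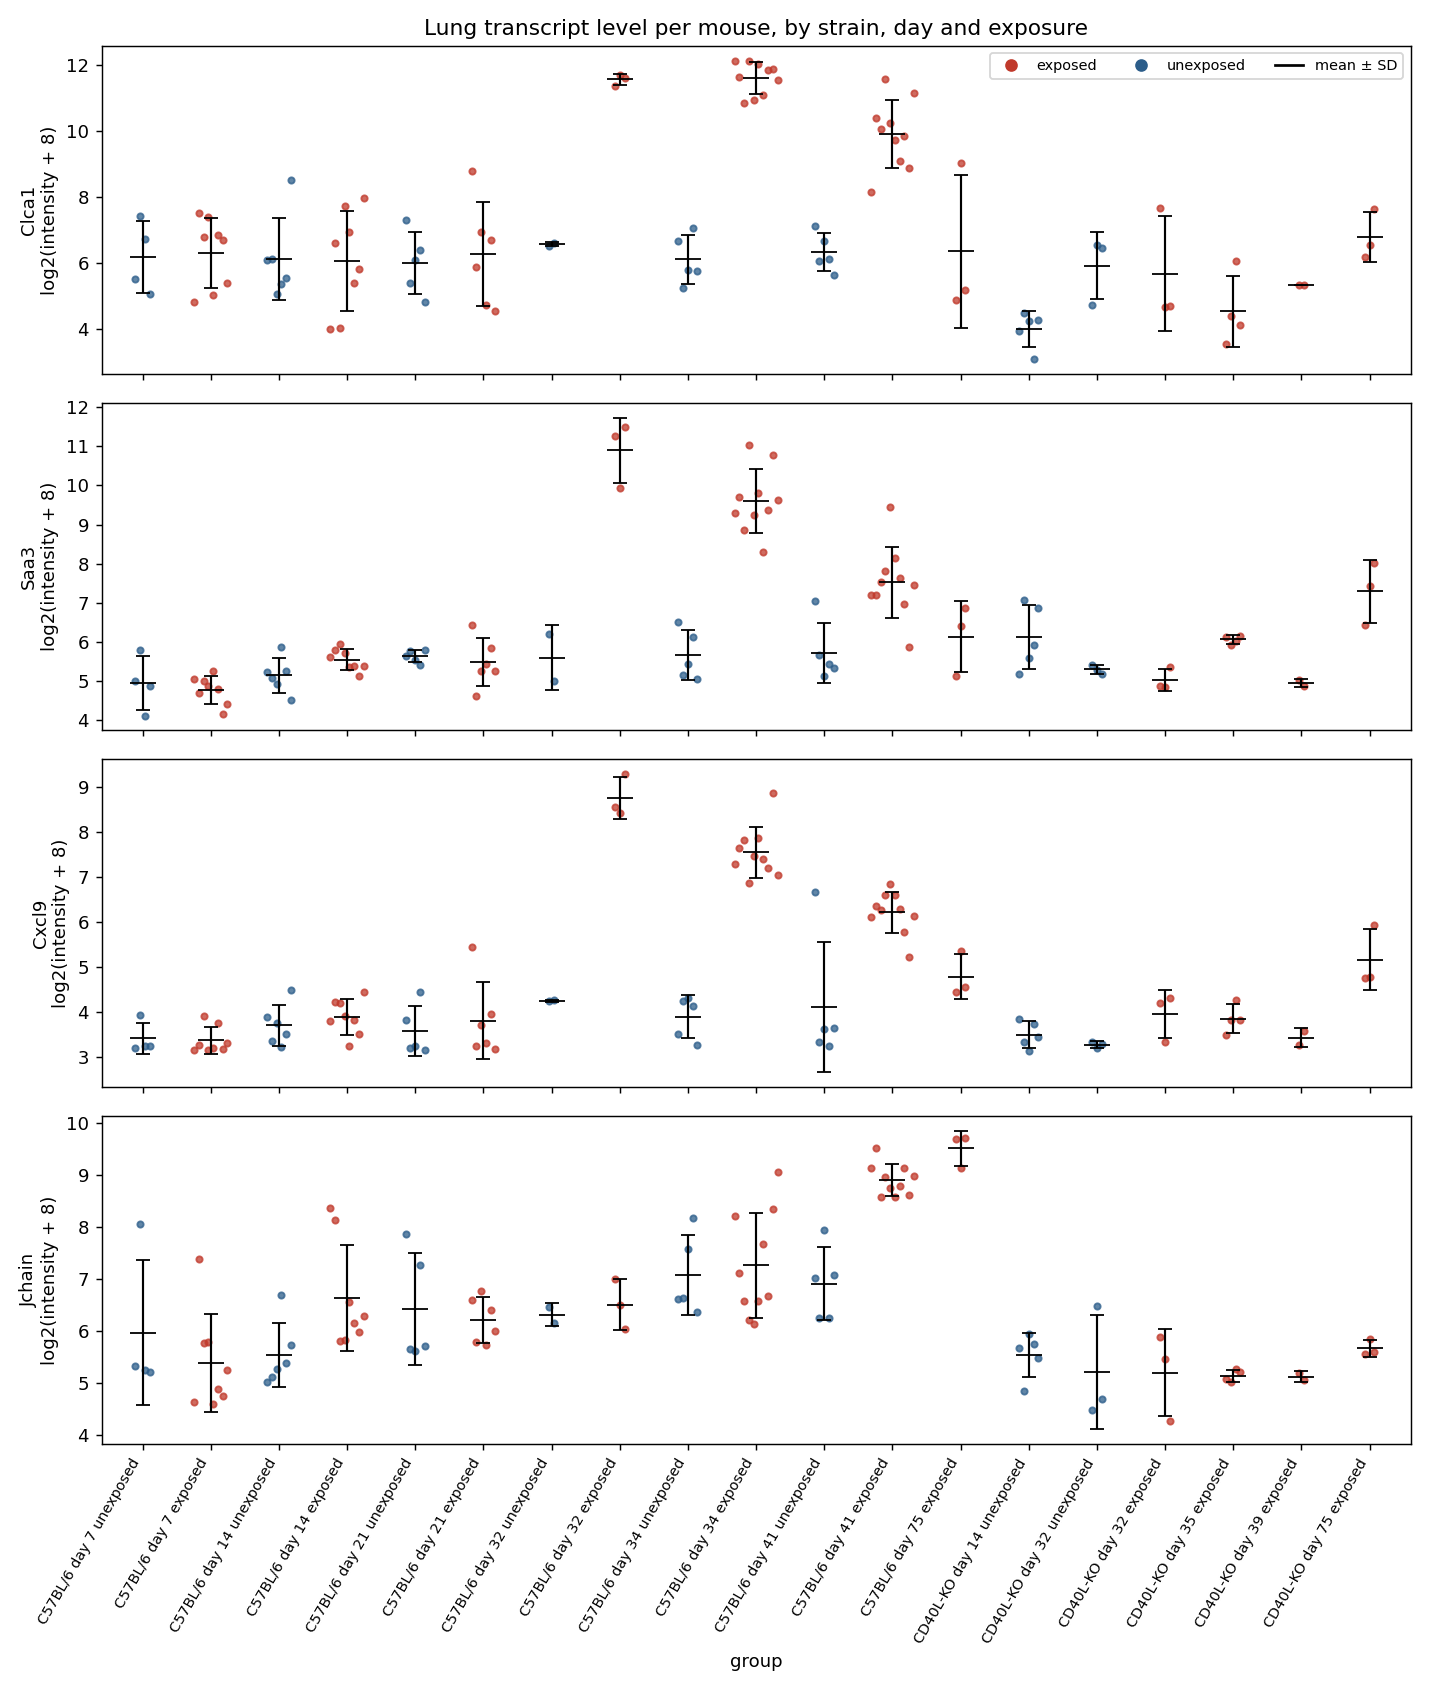
Level of Clca1, Saa3, Cxcl9 and Jchain in each mouse, as log2(intensity + 8), by group on the horizontal axis, with points for mice and bars for mean ± SD. Clca1 averaged 11.57 and 11.62 in C57BL/6 mice exposed for 32 and 34 days, and 5.68 in CD40L-KO mice exposed for 32 days.

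The second experiment repeated the exposure in C57BL/6 mice with 10 exposed and 5 unexposed mice at day 34. Clca1 was again far higher, by 5.51 (SE 0.39, adjusted p = 7.25e-11), with its other probe set at 0.59. Saa3 rose by 3.95, Cxcl9 by 3.64, Ccl8 by 3.07 and Cxcl5, a neutrophil chemokine, by 2.12, each in 10 of 10 mice. Lcn2, an iron-scavenging protein associated with neutrophil gelatinase, rose by 2.86 while its dimmer probe set gave -0.32. It lay between 6.53 and 8.0 in these unexposed mice, against 8.56 to 9.35 in the unexposed mice of day 41. The size of its rise thus depends on low controls. Among Th1 and interferon-gamma genes 21 of 33 rose, 23 when adjusted over the list alone with 1 lower there (fry adjusted p = 5.25e-09), and Gbp2 and Igtp did so by 1.63 and 2.01. Of 34 macrophage and monocyte genes 19 rose, 26 when adjusted over the list alone (fry adjusted p = 4.31e-06). In the MHC class II list 7 of 13 rose, 8 when adjusted over the list alone, and in the type 2 and alternative activation list 9 of 22, 10 when adjusted over the list alone, including the chitinase-like Chil3 by 1.46 (fry adjusted p = 4.31e-06 for both). Cell cycle genes rose in 19 of 41 cases, 29 when adjusted over the list alone (fry adjusted p = 4.25e-05), with Birc5 at 1.4 and Mki67 at 1.38, whose other probe set gave -0.35. T cell genes rose in 7 of 28 cases, 8 when adjusted over the list alone, among them Cd3e by 1.24 (fry adjusted p = 0.00054, adjusted p = 0.0705 with an estimated correlation). Lower transcripts included the glutathione transferase Gsta4, which fell by 1.28, Cyp1a1 by the same amount with its other probe set at 0.54, and the clock gene Cry1, which fell by 0.57 with its other probe sets from -0.25 to 0.03 and stood at 0.37 (adjusted p = 0.151) with the unexposed mice of days 34 and 41 pooled and squamous arrays left out.

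At this day 434 genes were higher and 244 lower. Of the 111 genes higher at day 32, which had other mice and controls, 82 were among them where 5.84 are due for independent lists, and of the 25 lower genes 6, where 0.739 are due. The Gapdh 3' to 5' ratio ranged from 1.21 to 4.42 in the unexposed mice and from 0.9 to 3.02 in the exposed mice, and 4 of 5 unexposed against 3 of 10 exposed arrays carried squamous transcripts. With that ratio as a covariate 184 genes passed, with the squamous score 316, with both tissue scores 325, and without the squamous arrays, which left 1 unexposed array, 17; with all arrays in 1 fit 1279 passed, and with the unexposed mice of days 34 and 41 pooled and squamous arrays left out 432, of which 187 were shared. The count was 449 without unexposed replicate 2 and 1313 without unexposed replicate 5.

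By day 41, with 10 exposed and 5 unexposed mice, antibody transcripts were among the higher genes. Igha, the constant region of IgA, rose by 2.46 (SE 0.33, adjusted p = 4.26e-05), the variable segment Ighv1-54 by 3.36 (SE 0.41) and Jchain, which joins IgA and IgM units, by 2.0 (SE 0.38, adjusted p = 0.00714), each in 10 of 10 mice. Clca1 rose by 3.6, its other probe set giving -0.11, Ccl8 by 2.1 and Cxcl9 by 2.11. Adck1, a kinase-like gene with a level of 7.7 against 5.68, rose by 2.01. Of 21 immunoglobulin and plasma cell genes 3 rose, 6 when adjusted over the list alone (fry adjusted p = 0.00267). Macrophage and monocyte genes rose in 4 of 34 cases, 18 when adjusted over the list alone, and Th1 and interferon-gamma genes in 2 of 33 cases, 17 when adjusted over the list alone (fry adjusted p = 0.00267 for both). Cxcr3, a receptor for Cxcl9, rose by 0.85 and the cathepsin Ctss by 0.81. In total 32 genes were higher and 0 lower in limma's test, with 610 genes at an unadjusted p under 0.05. Lower genes numbered 1 with the lower offset, 2 with the mean of all probe sets, 1 without squamous arrays, 10 with all arrays in 1 fit and up to 3 with 1 array left out. The count in both directions was 18 and 20 without unexposed replicate 2 and 5 and 96 with all arrays in 1 fit.

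The change of the exposure effect between the days was tested within the second experiment. Igtp and Ifi47, interferon-inducible GTPases, had smaller effects at day 41, by -1.38 (SE 0.28, adjusted p = 0.0267) and -1.11 (SE 0.23), as did Lcn2, by -1.81, with its other probe set at 0.34. Lcn2 averaged 10.25 and 9.95 in exposed mice of days 34 and 41 against 7.39 and 8.9 in unexposed mice, Igtp 8.2 and 7.37 against 6.19 and 6.75, and Ifi47 8.13 and 7.56 against 6.72 and 7.26. Cyp1a1 averaged 6.38 and 7.21 against 7.66 and 6.74. Ighv1-54 had a larger effect, by 3.01 (SE 0.58, adjusted p = 0.0213). Cry1 differed by 0.92 (SE 0.12, adjusted p = 0.000141), with unexposed means of 8.02 ± 0.14 at day 34 and 6.91 ± 0.16 at day 41 (SD, n = 5 each) and other probe sets from -0.03 to 0.43, and Cyp1a1 by 1.74, against -0.55 in its other probe set. Of 33 Th1 and interferon-gamma genes 2 had a lower effect, 14 when adjusted over the list alone (fry adjusted p = 0.0106, adjusted p = 0.158 with an estimated correlation). Jchain, at 1.81, and Clca1, at -1.91, did not pass (adjusted p = 0.208 and 0.203). Defa35, at 1.6, Ppie, at -1.14, and Serpina3n, at -1.07, completed the 4 higher and 5 lower effects, the names of Defa35 and Ppie chosen after their values were seen. Defa35 averaged 4.0 and 4.09 in exposed against 5.47 and 3.96 in unexposed mice of days 34 and 41, Ppie 5.15 and 5.17 against 4.21 and 5.36, and Serpina3n 8.49 and 7.92 against 7.68 and 8.18. Squamous transcripts were on 4 of the 5 unexposed arrays of day 34 and on 0 of those of day 41. The count was 14 without day 34 exposed replicate 7, 105 without day 34 unexposed replicate 5, 3 without day 41 unexposed replicate 2, 2 with the Gapdh ratio, 4 with the squamous score and 5 with both tissue scores as covariates, 4 without squamous arrays, 5 with the mean of all probe sets and 178 with all arrays in 1 fit.

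The third experiment followed C57BL/6 mice at days 7, 14 and 21. At day 7 the genes that led later comparisons were close to their unexposed levels in 8 exposed against 4 unexposed mice, with Cxcl9 at -0.04 (SE 0.3), Clca1 at 0.12 (SE 0.75) and the neutrophil protein S100a8 at 0.5 (SE 0.44). Limma called 0 genes, 545 had an unadjusted p under 0.05, and 0 of 29 lists passed. Other settings gave at most 2 genes, camera called 0 lists, and leaving out unexposed replicate 2 or 4 gave 4 and 1.

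Exposure for 14 days, with 8 exposed and 6 unexposed mice, was followed by higher Igha, Rsad2 and Ccl5. Igha rose by 1.72 (SE 0.28, adjusted p = 0.00103), Rsad2, an antiviral interferon-induced enzyme, by 1.58 (SE 0.27, adjusted p = 0.00142) and the chemokine Ccl5 by 0.99 (SE 0.2), each in 8 of 8 mice. Of 15 type I interferon genes 3 rose, 6 when adjusted over the list alone (fry adjusted p = 0.00122), with Irf7 at 0.8 and Isg15 at 0.67. Cytotoxic and natural killer genes rose in 2 of 22 cases, 11 when adjusted over the list alone, and erythroid genes in 1 of 17 cases, 9 when adjusted over the list alone (fry adjusted p = 0.00982 for both); that erythroid gene was Slc4a1, the red cell anion exchanger, at 1.42. The smooth muscle genes Myh11 and Tagln fell by 0.83 and 0.72 and the clock gene Per2 fell by 0.67. Granzymes D, F and G were higher by 2.73, 1.77 and 2.18; these names were chosen after their values were seen. Cxcl9 stood at 0.19 (SE 0.26) and Clca1 at -0.06 (SE 0.67). In all 18 genes were higher and 4 lower. The count was 13, 51, 13 and 14 without exposed replicate 4, 6, 7 and 8, and 12, 10 and 14 without unexposed replicate 2, 4 and 6; it was 14 with the Gapdh ratio as a covariate, 13 without squamous arrays and 38 with all arrays in 1 fit.

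At day 21, with 6 exposed and 5 unexposed mice, S100a8 differed by 1.71 (SE 0.43) and Cd8a by 0.75 (SE 0.23), above the unexposed mean in 6 of 6 mice and short of the threshold (adjusted p = 0.152 and 0.239). Type I interferon genes rose in 0 of 15 cases, 5 when adjusted over the list alone (fry adjusted p = 0.0415, adjusted p = 0.225 with an estimated correlation). The T cell list, 0 of 28 past the threshold and 0 when adjusted over the list alone, moved up with fry adjusted p = 0.0415 and adjusted p = 0.225 with an estimated correlation. Limma called 0 genes, with 959 at an unadjusted p under 0.05. Other settings gave up to 5 genes; the count was 7 without exposed replicate 3, 1 without unexposed replicate 1, 2, 3 or 4 and 2 without unexposed replicate 5.

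The fourth experiment returned to CD40L-KO mice, with 4 exposed for 35 days and 5 unexposed mice that the labels place at day 14, so that age or day differs with exposure. Cxcl9 differed by 0.35 (SE 0.19, adjusted p = 0.588), Clca1 by 0.53 (SE 0.46), Cxcl10 by 0.14 (SE 0.2) and Cd3e by 0.51 (SE 0.45). The list of alveolar epithelium and surfactant genes moved up, with 0 of 17 past the threshold and 0 when adjusted over the list alone (fry adjusted p = 0.0276, adjusted p = 0.184 with an estimated correlation); Sftpc, surfactant protein C, stood at 0.23 (SE 0.1). Limma called 0 genes, with 771 at an unadjusted p under 0.05, 3 with the lower offset, 21 with all arrays in 1 fit and 1 without unexposed replicate 4. In simulated data of this size, with 200 changed genes, 41 of 50 changed by 1 on the log2 scale and 50 of 50 changed by 2 were found. The noise there was independent between genes. With fewer changed genes, or genes that vary together, the shares found could be lower.

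Set against C57BL/6 mice at day 34, from another experiment, this effect was smaller for the genes that led there. Strain, experiment and sex pattern cannot be told apart in this comparison. All of its CD40L-KO arrays showed the male pattern and all of its C57BL/6 arrays the female pattern. In addition, the labels place the unexposed CD40L-KO mice at day 14 and the exposed ones at day 35. The unexposed mice also differed, with squamous transcripts on 4 of 5 C57BL/6 and 1 of 5 CD40L-KO arrays. Their Gapdh 3' to 5' ratios were 1.21 to 4.42 and 0.94 to 1.19. Clca1 differed by -4.98 (SE 0.54, adjusted p = 1.43e-05), with other probe sets at -0.49, Saa3 by -4.01 (SE 0.57), Cxcl9 by -3.29 (SE 0.38) and Ccl8 by -2.9 (SE 0.38). Of 33 Th1 and interferon-gamma genes 9 had a lower effect, 19 when adjusted over the list alone (fry adjusted p = 1.91e-05). Cell cycle genes had a lower effect in 6 of 41 cases, 13 when adjusted over the list alone (fry adjusted p = 0.000239), Birc5 by -1.83. MHC class II genes had a lower effect in 1 of 13 cases, 3 when adjusted over the list alone (fry adjusted p = 0.0158, adjusted p = 0.146 with an estimated correlation). Ogn, an extracellular matrix proteoglycan, had a higher effect by 1.05 and Egr1 by 1.72, its other probe set giving -0.66. In all 9 genes had a higher and 39 a lower effect. The count was 30 and 88 without C57BL/6 unexposed replicate 2 and 5, 14, 20, 29 and 26 without CD40L-KO exposed replicate 1 to 4, 22, 30 and 20 without CD40L-KO unexposed replicate 2, 3 and 5, 20 with the Gapdh ratio as a covariate, 4 without squamous arrays and 325 with all arrays in 1 fit.

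Unexposed CD40L-KO and C57BL/6 mice labelled day 14, from different experiments, with 5 and 6 mice, differed in 3176 of 8252 genes. Xist was lower by -4.98 (SE 0.32, adjusted p = 1.29e-06) and Eif2s3y higher by 3.34 (SE 0.15) in the CD40L-KO mice, where each CD40L-KO array showed the male pattern. Among immune genes Ifi204, an interferon-inducible sensor gene, was higher by 2.58, with other probe sets from -0.08 to 0.5, and Cd79a, a B cell receptor subunit, by 0.97. MHC class II genes were higher in 8 of 13 cases, 8 when adjusted over the list alone (fry adjusted p = 0.00112, adjusted p = 0.771 with an estimated correlation). Collagen VI genes Col6a1 and Col6a2 were lower by -1.2 and -1.22, in a fibroblast and extracellular matrix list with 3 higher and 14 lower of 35, and 3 and 16 when adjusted over the list alone (fry adjusted p = 0.00112, adjusted p = 0.771 with an estimated correlation). Cell cycle genes were higher in 3 and lower in 20 of 41 cases, with the same counts when adjusted over the list alone (fry adjusted p = 0.0019, adjusted p = 0.771 with an estimated correlation). In the dendritic cell list 3 genes were higher and 9 lower of 21, with the same counts when adjusted over the list alone; its median of 0.045 and mean of -0.186 differ in sign, and its fry test gave the lower direction (adjusted p = 0.0196, adjusted p = 0.83 with an estimated correlation). Per2 was lower by -1.21 and Gas5 by -2.58. In all 1454 genes were higher and 1722 lower, against 1599 and 1496 with quantile normalization, so the larger direction depends on the scaling. Experiment, strain and sex pattern cannot be told apart in this comparison. In other mice the median change of these genes, signed by their direction here, was -0.02 between unexposed strains at day 32. Between sex patterns of CD40L-KO mice it was 0.05. Here the median size was 0.57, which argues against sex pattern alone as the cause of the whole difference.

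Mice sampled at days 39 and 75 have no unexposed mice of those days and no stated experiment, so the unexposed mice of day 32, from experiment 1, served and experiment can differ as well as day. All of these later mice showed the male pattern where those of day 32 showed the female pattern. In 3 C57BL/6 mice of day 75, antibody transcripts were higher than in 2 unexposed mice. Igha rose by 2.47 (SE 0.35, adjusted p = 0.00258), Jchain by 3.2 (SE 0.51) and Igkv6-14 by 3.98 (SE 0.41), with its other probe set at -0.23, each in 3 of 3 mice. The kinase-like gene Adck1 rose by 2.46, also in 3 of 3 mice. Of 21 immunoglobulin and plasma cell genes 2 rose, 4 when adjusted over the list alone (fry adjusted p = 0.00173). Elastin, Eln, fell by 1.6 and Col1a1 fell by 0.66, and 3 of 35 fibroblast and matrix genes fell, 8 when adjusted over the list alone (fry adjusted p = 0.00575, adjusted p = 0.174 with an estimated correlation). Cxcl9 stood at 0.54 (SE 0.38) and Clca1 at -0.21 (SE 1.05), and Xist fell by 3.22. The Gapdh ratio was 1.1 to 1.2 in the day 75 and 0.91 to 0.95 in the unexposed mice. In all 83 genes were higher and 38 lower. The count was 29 and 23 without day 75 replicate 1 and 3, 28 and 41 without unexposed replicate 1 and 2, 207 with the higher offset, 182 without dim genes, 75 without squamous arrays, 65 with all arrays in 1 fit, 24 with both tissue scores and 9 with the Gapdh ratio as covariates.

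CD40L-KO mice of day 75 were compared as 3 against 3 unexposed. Ccl8 rose by 3.03 (SE 0.47, adjusted p = 0.00235), Saa3 by 2.0 (SE 0.48), Cxcl9 by 1.88 (SE 0.34), the scavenger receptor Marco by 1.41 and the protease Ctsk by 1.8, each in 3 of 3 mice. Macrophage and monocyte genes rose in 6 of 34 cases, 9 when adjusted over the list alone (fry adjusted p = 0.0392, adjusted p = 0.714 with an estimated correlation), and B cell genes in 4 of 18 cases, 9 when adjusted over the list alone (fry adjusted p = 0.00656, adjusted p = 0.337 with an estimated correlation), with Blk at 0.89 and Cd22 at 0.8. Jchain differed by 0.45 (SE 0.46, adjusted p = 0.603). Krt13 and Krt4, keratins of squamous epithelium, fell by 5.35 and 4.37, other probe sets of Krt13 ranging from -4.97 to 0.58 and Krt4 standing at 0.27 with the squamous score and 0.13 with both scores as covariates, the muscle myosin gene Myl3 fell by 4.06, and 2 of the 3 unexposed arrays carried squamous transcripts. In all 460 genes were higher and 236 lower; 27 passed with the squamous score as a covariate, 10 with both tissue scores, and 21 without the squamous arrays, which left 1 unexposed array. The count was 451, 223 and 251 without day 75 replicate 1, 2 and 3 and 272 without unexposed replicate 2.

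In the 2 CD40L-KO mice of day 39 the B cell kinase Blk rose by 1.07 (SE 0.18, adjusted p = 0.0438), and Xist fell by 2.99. Asrgl1, at 0.95, Eif2s3y, at 2.08, and Sfrp1, which fell by 1.25, completed 3 higher and 2 lower genes, and were named after their values were seen. B cell genes rose in 1 of 18 cases, 8 when adjusted over the list alone (fry adjusted p = 0.0315, adjusted p = 0.18 with an estimated correlation). Cxcl9 stood at 0.15 (SE 0.38) and Clca1 at -0.6 (SE 1.05). The count was 1 without day 39 replicate 1, 3 without unexposed replicate 1 or 2, 82 without unexposed replicate 3, 3 without dim genes, and 2 with the squamous score, both tissue scores or the Gapdh ratio as covariates.

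**Figure D3:**
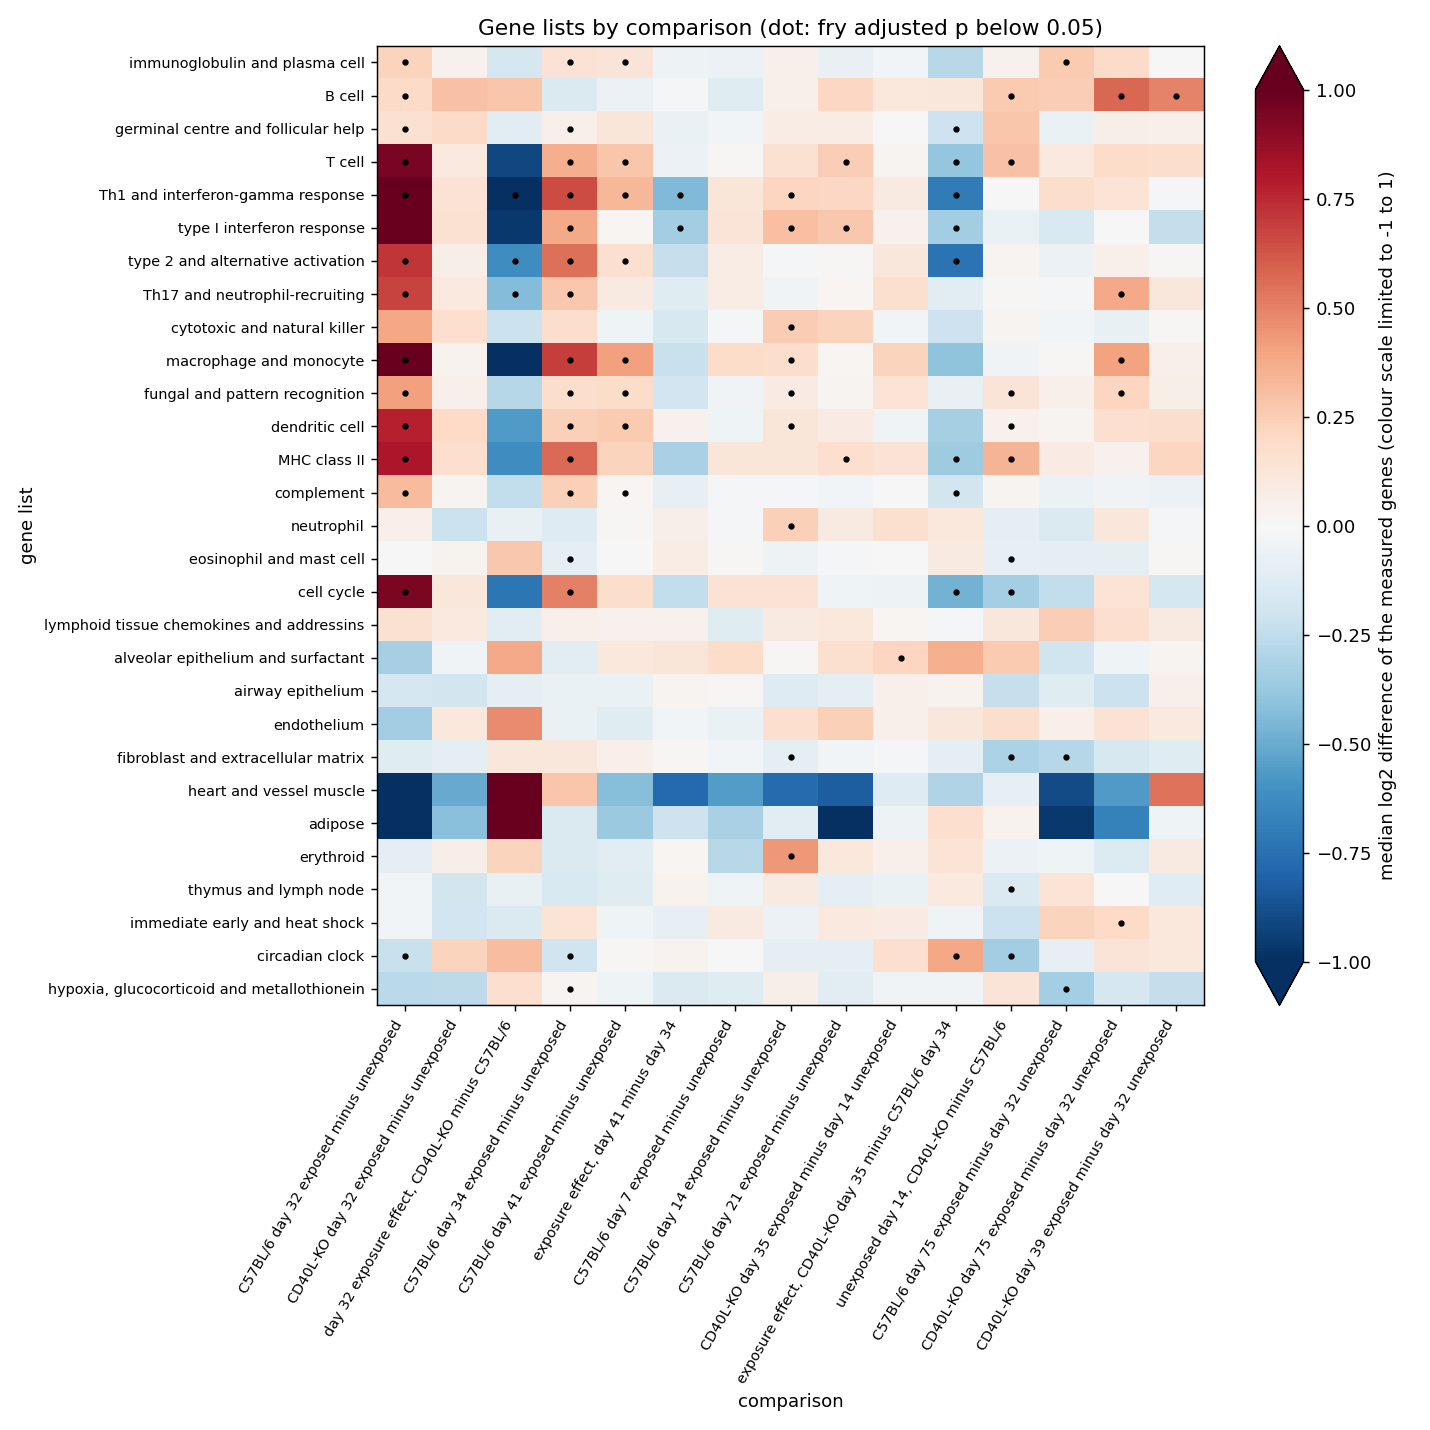
Median log2 difference of the measured genes of 29 gene lists (vertical axis) in the 15 comparisons (horizontal axis), as colour limited to -1 to 1, with a dot where the fry test passed. The Th1 and interferon-gamma list carries a dot at days 32, 34, 41 and 14 of exposure in C57BL/6 mice and none in the CD40L-KO exposure comparisons. In camera, which compares a list with the other genes, it passed neither at day 32 in C57BL/6 mice nor in the strain difference of that day.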

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

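The tests of explanations for the day 34, unexposed day 14 and granzyme patterns, with their marker lists and covariates, were chosen after the patterns were seen, and those with the squamous score at day 34, of strain, of the size of the change for sex, of the granzyme spread and of granzyme levels on squamous arrays also after their own results were seen.

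Among 352 pairs of a named gene and a group of 4 to 10 mice, 24 held a mouse far from the others, where chance gives about 1 in 20. In exposed C57BL/6 mice of day 34, replicate 4 was apart for Ccl9, Timp1 and Serpina3n at 10.73, 9.74 and 9.38, and replicate 9 for Cxcl9 at 8.86. In the unexposed mice of that day, replicate 1 was apart for Gbp2 and Pax5 at 6.45 and 7.46, replicate 2 for Agr2 and Tff2 at 3.3 and 5.85, and replicate 3 for Ccl8 at 4.42. In unexposed mice of day 41, replicate 3 was apart for Igkv9-120, Igkv14-111 and Igkv6-14 at 7.21, 7.72 and 7.87, and replicate 1 for Cxcl9 at 6.67. Cxcl9 also set apart day 7 unexposed replicate 2, at 3.94, and day 21 exposed replicate 1, at 5.44. At day 14, exposed replicate 5 was apart for Per2 at 4.97, and among unexposed C57BL/6 mice replicate 6 for Clca1 and Mir686 at 8.53 and 8.91, replicate 4 for Psca at 4.45 and replicate 5 for Cap1 at 5.22. In CD40L-KO mice, unexposed replicate 1 was apart for H2-Eb1 at 9.81 and replicate 3 for Cd79a at 8.69, and day 35 exposed replicate 1 for Gbp2 at 7.78 and replicate 2 for Birc5 at 4.04.

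The exposure effect differed by a test of the difference itself in 14 genes between strains at day 32, in 9 genes between days 41 and 34, and in 48 genes between CD40L-KO mice at day 35 and C57BL/6 mice at day 34. Probe sets with no gene name or several, 1589 in all, entered no comparison of the report; of them 22 passed in C57BL/6 mice at day 32, 2 in the strain difference at day 32, 67 at day 34, 31 at day 41, 4 at day 14, 2 at day 21, 5 in the difference between day 35 and day 34, 518 between unexposed strains, 53 and 86 at day 75 in C57BL/6 and CD40L-KO mice and 1 at day 39.

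The 244 genes lower in exposed C57BL/6 mice at day 34 had a median change of -0.54 with a median SE of 0.14. With the Gapdh ratio as a covariate 23 were still called as the median change shrank to -0.38 with SE 0.15, and the median of the 434 higher genes went from 0.64 to 0.49, so a difference in RNA quality may account for part of the change in both sets, while the number of lost calls overstates that part. With the squamous score as a covariate 95 were still called, at a median of -0.49 with SE 0.16, which leaves tissue from outside the lung open; the mean of its 9 markers was at most 5.25 on arrays without squamous transcripts, against 6.12 for the median gene. All 244 kept their direction under both, and of the higher genes 138 were still called with the ratio and 185 with the score. The effect of exposure itself stays open, as RNA quality, tissue and exposure overlap in the 5 unexposed mice.

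Unexposed CD40L-KO and C57BL/6 mice labelled day 14 differed in 3176 genes. Between the unexposed strains at day 32, 46.9% of them had the same sign, 45% to 49.5% with 1 array left out. The median there was -0.02 against 0.57, which argues only against a difference shared by both days. That check rests on 3 CD40L-KO mice, 2 of them with squamous transcripts, and 2 C57BL/6 mice without. The transcript Nnt, named after its values were seen, averaged 7.32 in those C57BL/6 mice and 5.84 in the unexposed C57BL/6 mice of day 14. The C57BL/6 mice thus differed too, and strain at day 14 cannot be judged from day 32. Between exposed CD40L-KO mice of day 35 and C57BL/6 mice of day 34, arrays not used in the comparison, 93.5% had the same sign, as when experiment 4 stands apart, but those mice also differ in strain and sex pattern. For sex pattern, CD40L-KO mice of days 39 and 75 with the male pattern were set against those of day 32 with the female pattern. The median was 0.05, with 0.03 to 0.06 when 1 array was left out and an SD of 0.3 over the genes, again against 0.57. There 58.1% had the same sign, a share that the rule set beforehand left undecided. By the size of the change, a criterion added afterwards, this argues against sex pattern alone as the cause of the whole difference. Those mice also differ in day and may differ in experiment, which could offset an effect of sex. Experiment, strain at that age and sex pattern as the cause of a part stay open.

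Granzymes D, F and G were higher at day 14 by a mean of 2.23, and Gzmd, Gzmf and Gzmg lay above every unexposed array in 7, 6 and 6 of 8 exposed mice. Over those mice the spread of each gene around the mean of the 3 was 0.12 of the spread of that mean, so 1 transcript read by the probe sets of all 3 paralogs is a candidate explanation, and the number of genes involved stays open. Tissue that brings squamous transcripts is argued against, since 0 of the 8 exposed arrays carried them and the mean level of the 3 genes, at most 4.23 on the 16 arrays of the series that did, was above that in 6 of the 8; with the squamous score as a covariate the change was 2.21. Tissue without those transcripts was not tested, and a response to exposure stays open.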

How the results depend on the processing

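The alternatives with tissue scores, with the Gapdh ratio and without squamous arrays, and those marker lists, were chosen after the results were seen. Counts of called genes follow, against main counts of 136, 6 and 14 at day 32 (C57BL/6, CD40L-KO, difference), 678 and 32 at days 34 and 41 with 9 for their difference, 0, 22 and 0 at days 7, 14 and 21, 0 for CD40L-KO day 35 with 48 for its difference from day 34, 3176 between unexposed strains, and 121, 696 and 5 at C57BL/6 day 75, CD40L-KO day 75 and CD40L-KO day 39; the cause of a change was not tested unless given. The lower offset gave 2 and 3 for CD40L-KO and the difference at day 32 and 3 at day 35. The higher offset gave 209, 13 and 27 at day 32, 1 at day 7, 4 at day 21 and 207 at C57BL/6 day 75. Without dim genes, where fewer genes are tested, there were 225, 26 and 25 at day 32, 1 at day 7, 3 at day 21, 182 at C57BL/6 day 75 and 3 at day 39. Quantile normalization gave 3 for CD40L-KO day 32 and 2 at day 7, and the mean of all probe sets 3 and 9 for CD40L-KO and the difference at day 32, 5 for day 41 against 34 and 2 at day 7. A single fit of all arrays, which shares the spread over 95 arrays, gave 733, 86 and 301 at day 32, 1279, 96 and 178 for days 34, 41 and their difference, 38 and 5 at days 14 and 21, 21 and 325 for day 35 and its difference, and 65 at C57BL/6 day 75. The replicate number did not pair arrays, as in 0 of 12 pairs of groups did every same-numbered pair correlate above 0.1; as a block it gave 42, 0 and 3 at day 32, 20 at day 41, 1 at day 7, 14 for day 35 against 34, 56 at C57BL/6 day 75 and 3 at day 39. The squamous score as a covariate gave 0 and 3 for CD40L-KO and the difference at day 32, 316 at day 34, 4 for its difference from day 41, 2 at day 7, 27 at CD40L-KO day 75 and 2 at day 39. Both tissue scores gave 4, 0 and 1 at day 32, 325 at day 34, 5 for its difference from day 41, 2 at day 7, 24 and 10 at day 75 and 2 at day 39. The Gapdh ratio gave 0 and 0 for CD40L-KO and the difference at day 32, 184 at day 34, 2 for its difference from day 41, 2, 14 and 1 at days 7, 14 and 21, 20 for day 35 against 34, 9 at C57BL/6 day 75 and 2 at day 39. Leaving out squamous arrays, which leaves 1 unexposed array at CD40L-KO day 32, at day 34 and for CD40L-KO day 75, assumed to vary like the other groups, gave 4, 0 and 0 at day 32, 17 at day 34, 4 for its difference from day 41, 13 and 2 at days 14 and 21, 4 for day 35 against 34 and 75 and 21 at day 75; with pooled controls day 34 gave 432. With 1 array left out, counts ranged from 6 to 584, 0 to 54 and 2 to 197 at day 32, 449 to 1313, 18 to 41 and 3 to 105 for days 34, 41 and their difference, 0 to 4, 10 to 51 and 0 to 7 at days 7, 14 and 21, 0 to 1 and 14 to 88 for day 35 and its difference, 2815 to 3337 between unexposed strains, 23 to 128 and 223 to 652 at day 75 and 1 to 82 at day 39. Named genes that changed sign were, at day 34 without squamous arrays, against that 1 unexposed array, Uqcrc2 at 0.73, Ifi35 at -0.01 and Egr1 at 0.21, and with pooled controls Uqcrc2 at 0.34 and Cry1 at 0.37; at CD40L-KO day 75, Mt4, Krt4 and Lgals7 at 0.17, 0.27 and 0.12 with the squamous score and at 0.16, 0.13 and 0.13 with both scores; Krt4 and Lgals7 are themselves among the markers of the score, and Mt4 is not. Of 289 named gene results, 276, 253 and 277 kept direction and side of the threshold with the higher offset, lower offset and quantile normalization, 229 with the squamous score, 189 with both scores, 212 with the Gapdh ratio and 122 without squamous arrays. Gene list calls by camera, which compares a list with the other genes, numbered 1 of 14 at C57BL/6 day 32, 5 of 16 at day 34, 6 of 8 at day 41, 8 of 9 at day 14, 3 of 9 for day 35 against 34, 1 of 3 at C57BL/6 day 75 and 0 in the remaining comparisons. Signal close to the offset limits the dimmest genes.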

Other observations

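The comparisons of the next paragraph with their covariates, the gene Nnt, and the counts of squamous arrays in splits of the mice, were chosen after the data were seen, while the splits of mice were planned before.

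Exposed CD40L-KO mice of day 75 were compared with those of day 39, all of the male pattern, 3 against 2, with a Gapdh 3' to 5' ratio of 1.1 to 1.21 at day 75 and 1.32 to 1.42 at day 39. Marco was higher by 1.66 (SE 0.22, adjusted p = 0.00526), the phagocyte oxidase subunit Ncf1 by 1.66, the cytokine receptor chain Csf2rb by 1.73, Saa3 by 2.36 and Cxcl9 by 1.74, while Jchain stood at 0.55 (SE 0.51) and Igha at 0.39 (SE 0.35); 194 genes were higher and 88 lower, 282 in all, and 1 passed with the Gapdh ratio as a covariate. Against C57BL/6 mice of day 75, also of the male pattern, CD40L-KO mice had less Igha, by -4.94 (SE 0.31, adjusted p = 4.96e-07), Jchain, by -3.85, and Igkv6-14, by -3.48, and more Marco, by 1.72, and Ctsk, by 1.31, among 7 higher and 20 lower genes with 3 mice each. Of 21 immunoglobulin and plasma cell genes 2 were lower there, 3 lower and 1 higher when adjusted over the list alone (fry adjusted p = 0.00315, adjusted p = 0.009 with an estimated correlation). The B cell list moved the other way, with 0 of 18 past the threshold and 6 higher when adjusted over the list alone (fry adjusted p = 0.00826, adjusted p = 0.0169 with an estimated correlation). The Th17 and neutrophil-recruiting list, 0 of 16 and 1 when adjusted over the list alone, and the fungal and pattern recognition list, 1 of 22 and 2 when adjusted over the list alone, also moved up (fry adjusted p = 0.005 for both, adjusted p = 0.009 and 0.0169 with an estimated correlation). These 4 of 29 lists passed, and 0 did between days 75 and 39 of CD40L-KO mice or between the unexposed strains at day 32. Between unexposed mice of day 32, in a fit of all mice of days 32, 39 and 75, Igha was lower in CD40L-KO mice by -3.22 (SE 0.35) and Nnt, a mitochondrial transhydrogenase, by -1.66 (SE 0.18), among 2 higher and 7 lower genes; squamous transcripts were on 2 of the 3 CD40L-KO and 0 of the 2 C57BL/6 arrays, the Gapdh ratio was 1.16 to 1.37 and 0.91 to 0.95, and 4 genes passed with either as a covariate. At day 14 Igha stood at 0.4 (SE 0.33, adjusted p = 0.37) between the unexposed strains.

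Nnt averaged 7.07, 6.86, 6.89 and 7.19 in exposed C57BL/6 mice of days 32, 34, 41 and 75, and 5.77, 5.86 and 5.81 in those of days 7, 14 and 21. Unexposed C57BL/6 mice were split in the same way, with means of 7.32, 6.99 and 6.88 at days 32, 34 and 41. At days 7, 14 and 21, which are all of experiment 3, they averaged 6.04, 5.84 and 5.74. The difference between these sets of days was thus there without exposure. Days 32, 34 and 41 are of experiments 1 and 2, so the split is also one between experiments. Day and experiment cannot be told apart in it. In exposed CD40L-KO mice of days 32, 35, 39 and 75 Nnt averaged 5.59, 6.3, 5.98 and 5.95. Unexposed CD40L-KO mice of days 32 and 14 averaged 5.67 and 6.4.

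Other splits of the same mice into groups of the same sizes were refitted, 100 where there are more. Among the splits drawn, 1, the real one, reached 678 at day 34 and 32 at day 41, with 469 and 7 as the highest others. The same held for 22 at day 14 and 3176 between unexposed strains, with 15 and 2. This argues against a random grouping of the mice for these counts, with mice taken as independent. For the differences of effects, 9 between days 41 and 34 and 48 for day 35 against day 34, the highest other was 1. Those splits also broke up the exposure effects themselves, so they cannot decide whether the effects are equal. The counts of 0 at days 7 and 21 and in CD40L-KO mice at day 35 are reached by any split, 100 of 100, so these splits say nothing about chance; the highest others were 1, 53 and 3. The split of day 21 with 53 genes, with squamous transcripts on 2 of the 5 arrays of its smaller side and 1 of the 6 of its larger side, points to a structure of the samples whose cause was not tested. So does the split of day 34 with 469 genes. It parted unexposed replicates 1, 2 and 4 and exposed replicates 7 and 9 from the other mice of that day. The Gapdh 3' to 5' ratios of these 5 were 4.42, 3.24, 2.4, 2.47 and 1.15, against 0.9 to 3.02 in the others. At CD40L-KO day 32 the 10 splits are too few, 2 of them reaching the real count of 6. The highest other, with 10 genes, parted the arrays by squamous transcripts, 3 of 3 against 0 of 3, and with the squamous score as a covariate the real count was 0. At CD40L-KO day 75 the 10 splits are likewise too few, 1 reaching 696, with 0 as the highest other.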
